A study of Mus musculus with 9 samples.

How the data were processed

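Gene expression was measured by RNA sequencing in 9 libraries of mouse haematopoietic stem cells, 3 from young wild-type (WT) mice aged 2 months, 3 from old WT mice aged 22 to 24 months and 3 from old mice of the same age range that carry the Sphk2 knockout (KO) named in the labels. Per the labels' protocols, each library came from 1000 marrow cells sorted as lineage-negative, Sca1- and c-Kit-positive, CD48-negative and CD150-positive, was amplified for 13 cycles after poly(A) tailing, and was read as pairs of 150 bp. The labels call the 3 libraries of each type technical replicates and give no mouse, litter or day, so p-values here measure only the spread between these samples, which may be technical.

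The authors deposited 1 table of raw read counts per gene, with 1 column per library. The submitters' processing notes name Trim Galore 0.6.2, STAR 2.6.1d, HTSeq 0.10.0, edgeR 3.24.3 and the mm10 genome. The gene annotation and the strand setting of the counting are not given in the sources used here. Reads of a gene and of an antisense partner could therefore not be told apart, and reads of near-identical genes could be split between copies. Besides 52550 gene identifiers, the table holds 5 lines that name no gene. The share of all counts outside annotated genes lay between 6.51% and 12.5% in young WT, 80.8% and 87.7% in old WT and 45.0% and 61.9% in old KO libraries. The ambiguous share lay between 0.619% and 5.48%. These lines stayed out of library sizes and tests. Symbols were found for 52403 identifiers, and coordinates and exon lengths come from the GENCODE M21 annotation of the same genome.

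Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. The main test was edgeR's quasi-likelihood F test on the deposited counts of all 9 libraries, with a mean per group, TMM factors, filterByExpr with the groups, and Benjamini-Hochberg adjustment at 0.05. It covered 32582 genes. The 3 comparisons were old WT against young WT, old KO against old WT, and old KO against young WT. Fold changes are log2 values with their standard error (SE), and levels are CPM, counts scaled to the library's total counts in genes, given as mean and SD of 3 libraries. In each comparison a positive fold change means a higher value in the group named first. Called means past the adjusted threshold.

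The test design, 40 gene lists and a rule for the genes to be named were fixed before the data were examined. The rule took the 10 largest called changes in each direction with non-overlapping ranges and a mean of at least 10 CPM in the higher group, up to 4 called members of each list or 2 members that were not called, and a fixed set that includes Sphk2, Gpx4 and Fth1. The text prints a subset of the genes that the rule gave, picked after their values were seen. Lists of at least 5 tested genes were compared with all other tested genes by camera on log2 CPM (prior count 3), with a preset correlation of 0.01 and again with an estimated one, adjusted over all lists and comparisons. Only 8582 genes were above the background defined below in at least 2 libraries of a group, while 32582 were tested. A list of expressed genes can therefore differ from other genes by camera for that reason alone.

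Because the share of counts outside genes differed between groups, a background was measured in each library as the read density over the exons of 1122 olfactory receptor genes, leaving out the densest 1%. A gene counted as above background in a library with at least 20 counts and at least 5 times the count that this density gives over its exons. Alternatives chosen after seeing the data subtracted this background and kept 8582 genes above it in at least 2 libraries of a group, thinned all libraries to the smallest total, or thinned young WT and KO libraries to the old WT level and added background to match. The matched libraries carry simulated noise. Alternatives fixed before the data were seen were DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio and exact tests, a robust fit, other scaling factors, other filters on low counts, thresholds, the 6 compared libraries alone, a replicate block, and leaving out each library. A further test, also chosen after seeing the data, set the median fold change of each list against 10000 random lists matched in 20 bins of young WT expression among 5825 genes above background in all young WT libraries (2-sided permutation test, adjusted over 33 lists in 2 comparisons). It draws genes as if they were independent, so its p-values measure the spread over genes and not that between libraries.

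The correlation between the ageing and the knockout fold changes was compared with 100 simulations of unchanged groups, since both use the old WT libraries. Scripts were tested on simulated counts with 200 genes changed by 4-, 16- or 64-fold. With the dispersions fitted to these libraries, old WT against young WT recovered 0%, 1.49% and 9.09% of the changed genes for these folds (25564 genes). Old KO against old WT (25577 genes) and old KO against young WT (26239 genes) recovered 0% at each. With a dispersion of 0.2, recovery was 35.8%, 97.0% and 100% for old WT against young WT, 32.8%, 92.5% and 98.5% for old KO against old WT, and 29.9%, 98.5% and 90.9% for old KO against young WT. The common dispersion of the real libraries was 0.887.

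Total counts in genes ranged from 3145167 to 74021822 per library. The widest 95% Wilson interval of the share outside genes reached 0.0185 percentage points on either side. Intervals and floors of 3 counts cover counting error only, because reads copied by PCR are not independent molecules. Comparisons of single values between 3 and 3 libraries used a 2-sided exact permutation test, whose smallest possible p is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.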

Results

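Haematopoietic stem cells, the marrow cells from which all blood lineages arise, were profiled in 3 groups of 3 libraries: young WT, old WT and old Sphk2 KO. Sphk2 encodes sphingosine kinase 2, which phosphorylates sphingosine, and the series title names sphingosine metabolism, ferroptosis and the rejuvenation of old stem cells. The counts in genes were 74021822, 28088637 and 31031106 in the young WT libraries, 5115003, 3145167 and 3448125 in the old WT libraries and 13457369, 11284847 and 17544945 in the old KO libraries. The libraries differed in how much of their sequence came from genes. Counts outside annotated genes made up 10.3% ± 3.29 of all counts in young WT, 83.6% ± 3.62 in old WT and 54.5% ± 8.61 in old KO libraries (SD, n = 3 each; exact permutation p = 0.1 for each pair of groups, the smallest this design allows). Olfactory receptor genes, which blood cells do not use, had 1.30 ± 0.163 reads per kb in young WT, 8.91 ± 2.79 in old WT and 6.63 ± 0.895 in old KO. The number of protein-coding genes above that background was 7755 ± 372 in young WT, 874 ± 233 in old WT and 3292 ± 736 in old KO. At matched depth and background the means were 2288, 795 and 1704 genes.

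**Figure D1:**
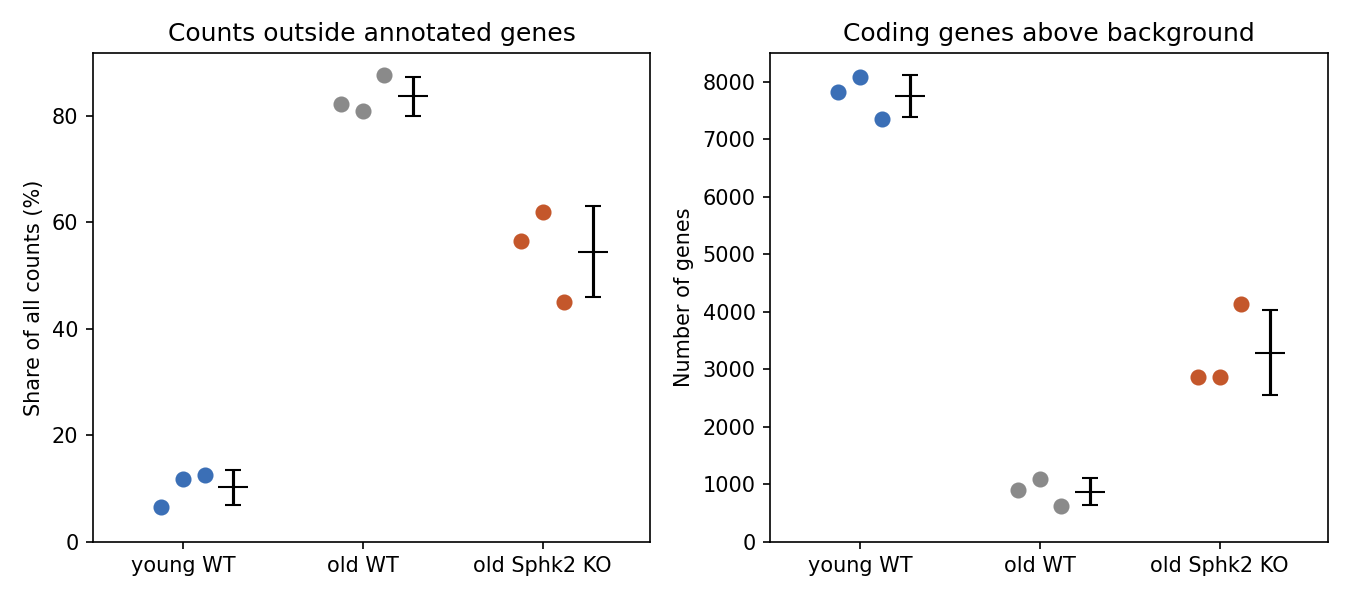
Share of all counts outside annotated genes (left, percent) and number of protein-coding genes above background (right) in each of the 9 libraries, with bars for the mean and SD of 3 libraries. The old WT libraries have the highest share, 80.8% to 87.7%, and the fewest genes, 625 to 1088, and the old KO libraries lie between them and young WT.

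Sphk2, the targeted gene (ENSMUSG00000057342, chromosome 7, 45709467 to 45718002, GRCm38), had 1684, 88 and 576 counts in the young WT libraries, 20, 1 and 35 in the old WT libraries and 12, 23 and 8 in the old KO libraries. It was above background in all 3 young WT libraries and in none of the 6 old libraries. Its fold change in old KO against old WT was -0.12 ± 1.31 (SE, n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.99998). Against young WT it was lower in old WT (-6.08 ± 1.62, adjusted p = 0.0155) and in old KO (-6.20 ± 1.63, adjusted p = 0.0356, same test). Without old WT library 1, 2 or 3 neither call was kept (-6.22, -5.66 and -6.90 for old WT), nor was the second without any old KO library. By CPM the young WT libraries had 22.8, 3.13 and 18.6 and the old WT libraries 3.91, 0.318 and 10.2, so these ranges overlapped. The old KO libraries had 0.892, 2.04 and 0.456 CPM. Over all genes TMM lay below total counts by a median of 3.92 log2 units for old WT and 2.01 for old KO against young WT. Since old WT reads of this gene did not rise above background, the counts cannot distinguish the knockout libraries from the old WT libraries, and the labels were not checked by it.

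The comparison of old WT with young WT asks how stem cells of old mice differ from those of young mice. A list of immediate early genes, which cells switch on quickly after a stimulus, and heat shock genes was lower in old WT with TMM factors. Of 34 members 32 were called lower (33 adjusted over the list alone), 26 of the 28 immediate early and all 6 heat shock genes. TMM lay below total counts by a median of 3.92 log2 units over all genes. By mean CPM, 29 of the 32 members above background in all young WT libraries were lower in old WT. Hspa1a (280 against 218 CPM), Dusp2 (855 against 777 CPM) and Socs3 (82.4 against 62.6 CPM) had higher means in old WT. After background removal 3 of 33 tested members were called lower. Fosb, a subunit of the AP-1 transcription factor (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), had 4603 ± 946 CPM in young WT and 65.4 ± 20.1 CPM in old WT (SD, n = 3 each), a fold change of -10.18 ± 1.01 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.4e-04). Krueppel-like transcription factors were lower as well: Klf4 (937 ± 125 against 20.9 ± 6.94 CPM), Klf6 (1585 ± 192 against 20.2 ± 9.47 CPM) and Klf2 (1676 ± 134 against 235 ± 76.9 CPM). Their fold changes were -9.53 ± 1.11, -10.28 ± 1.23 and -6.81 ± 0.98, each with an adjusted p of 0.0039 in the same test. Ier3, another early response gene, fell by a fold change of -10.42 (adjusted p = 0.0039, same test). Fewer genes were above background in old WT: of 1399 protein-coding genes with at least 50 CPM in every young WT library, 742 were above background in 0 old WT libraries, 350 in 1, 130 in 2 and 177 in 3.

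Other genes with the largest called falls, all from means of at least 128 CPM in young WT to under 10 CPM in old WT, were Hist1h1c, a linker histone, Pf4, a platelet chemokine, S1pr1, a receptor for sphingosine 1-phosphate, Mrfap1, Spry1, an inhibitor of receptor tyrosine kinase signalling, Tmem14c and Ddit3, a transcription factor of the integrated stress response. Their fold changes ran from -10.86 ± 2.16 for Pf4 to -10.30 ± 1.84 for Tmem14c (SE, n = 3 each). Genes of DNA replication and division were lower: 30 of 39 S phase genes, with Pcna, the replication clamp, at -10.03 ± 1.32, and 22 of 40 G2 and mitosis genes, with Ube2c at -9.52 ± 1.45 and Mki67 at -6.53 ± 1.26, the last not called with total counts (-2.32; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p between 0.0039 and 0.0060 for the 3 genes). Over the lists alone the counts were 32 and 22. Of 40 stem cell identity genes, 28 were lower (30 over the list alone), among them Kit, the stem cell factor receptor used in the sort (-7.69 ± 1.21), and Runx1 (-6.70 ± 1.17). These 3 lists lay within random lists of equal young WT expression (adjusted permutation p = 0.503, 0.305 and 0.912 for S phase, G2 and mitosis, and stem cell identity).

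Genes of the pathways in the series title were mostly lower or not called. Among 35 genes that protect from ferroptosis, an iron-dependent form of cell death, 20 were called lower, 2 higher and 13 not called (26 lower and 2 higher adjusted over the list alone). Fth1, the ferritin heavy chain that stores iron (ENSMUSG00000024661, chromosome 19, 9980598 to 9985098), fell from 2209 ± 373 to 875 ± 227 CPM, a fold change of -5.28 ± 0.89 (SE, n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0053), and the light chain Ftl1 from 641 ± 63.2 to 141 ± 97.7 CPM (-6.05 ± 1.19, adjusted p = 0.0063). Most of these values came from the TMM factors: with total counts Fth1 was at -1.31 and not called and Ftl1 at -2.16, and after background removal neither was called (-0.79 and -1.71). Gpx4, which detoxifies lipid peroxides, had 953 ± 58.7 CPM in young WT and 1297, 20.3 and 20.9 CPM in the 3 old WT libraries (-4.97 ± 1.49, adjusted p = 0.0232, same test). Without old WT library 1 Gpx4 was at -9.68, and without young WT library 1 or old WT library 2 or 3 it was not called. Of 40 ferroptosis-promoting genes 15 were lower and 1 higher (15 and 1 over the list alone). Those lower included Acsl4, which loads membranes with oxidisable fatty acids (-5.84 ± 1.70; not called without old WT library 1, 2 or 3 or with total counts, -1.89). Tfrc, the transferrin receptor, was not called in the main test (-3.52 ± 1.43, adjusted p = 0.0611). It was called lower without young WT library 1 (-4.14) and in 1 of 8 other settings, and its sign turned without a call in 2 of these 8. Among 43 sphingolipid enzyme genes, 17 were lower, 5 higher and 21 not called (20 and 6 over the list alone). Those called included the ceramide synthase Cers2 (-7.81 ± 1.84) and Ormdl3, a regulator of sphingolipid synthesis (-8.27 ± 1.43), while Sgpl1, the lyase that breaks down sphingosine 1-phosphate, was at 0.79 ± 1.15 and was not called. Of that list, 25 members were above background in at least 2 young WT libraries and 0 in at least 2 old WT libraries.

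Transcripts of the mitochondrial genome and of ribosomal proteins stood apart from genes of like expression. mt-Nd5 had 1745 ± 165 CPM in young WT and 1846 ± 433 CPM in old WT, and mt-Co1 9004 ± 1744 and 6152 ± 3189 CPM (SD, n = 3 each). With TMM factors their fold changes were -3.96 ± 0.85 and -4.44 ± 0.85 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0077 and 0.0059). With total counts as the only scaling, mt-Nd5 was at 0.10 (adjusted p = 0.890). TMM lies below total counts here by a median of 3.92 log2 units over all genes. Of 87 ribosomal protein genes 86 were called lower and 1 higher (86 and 1 over the list alone), with Rps2 at -5.25 ± 0.81 and Rpl10 at -5.35 ± 0.85 (SE, n = 3 each; -1.23 and -1.33 with total counts). Compared with random lists of equal young WT expression, ribosomal protein genes (median -4.40 against -5.77) and mitochondrially encoded genes (-3.12 against -5.04) lay higher, each with an adjusted permutation p of 0.0044. The estimated correlation between members was 0.573 and 0.687 in these lists, so their genes are not the independent draws that the permutation assumes. Erythroid genes lay lower (-8.36 against -5.43 over 6 members, adjusted permutation p = 0.0066). Of these 6, 2 had old and young WT ranges that did not overlap (33.3%, against 36.6% of other genes). Only 1 erythroid gene was above background in at least 2 old WT libraries, so this median mostly rests on reads near background. After background removal the erythroid list did not pass by camera (adjusted p = 0.343). Immediate early and heat shock genes had a median of -6.50 against -5.35 (adjusted permutation p = 0.0874), and the sphingolipid and ferroptosis lists lay within the random range. By camera 29 of 37 lists were lower than other genes, and 26 kept the call with an estimated correlation. Those that lost it were the erythroid (adjusted p = 0.0581 with an estimated correlation), mitochondrially encoded (0.0980) and ribosomal protein lists (0.0609). After background removal 0 lists were lower and 2 higher, the mitochondrially encoded and ribosomal protein lists, and 0 kept the call with an estimated correlation.

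Genes reported as markers of old stem cells were not higher as a group: of 50 such genes 16 were lower, 4 higher and 30 not called (16 and 4 over the list alone). Selp, Vwf, Aldh1a1 and Procr had fold changes of -3.84 ± 1.52, -3.02 ± 1.26, -2.59 ± 1.70 and -3.15 ± 1.64 and were not called. With total counts they were at 0.31, 0.98, 1.26 and 0.96. Selp (-6.90) and Procr (-8.10) were called lower without old WT library 1 and Aldh1a1 (-6.77) without old WT library 2. Mecom was not called (-2.67 ± 1.46, and 0.03 without young WT library 1), and Clu was lower (-8.16 ± 1.43; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0053). Hlf, a stem cell transcription factor, was at -4.05 ± 1.46 (adjusted p = 0.0422) with TMM and at 0.52 (adjusted p = 0.732) with total counts. Hlf was at -7.95 without old WT library 3 and not called without any other young or old WT library. Slamf1, which encodes the CD150 of the sort, was at -0.26 ± 1.43 (adjusted p = 0.879) with TMM and at 3.93 (adjusted p = 0.0415) with total counts, and it was above background in 1 old WT library. Of 28 genes reported to be lower in old stem cells 16 were lower (19 lower and 2 higher over the list alone), including Nkg7 (-9.78 ± 1.66, adjusted p = 0.0053). Across the genome 6060 genes were called higher in old WT, of which 99.2% were not above background in at least 2 old WT libraries and 399 were olfactory receptors. Among those with the largest rises, Tmem52 and Olfr1010 had 0 counts in all young WT libraries. They were at least 582-fold and 373-fold higher in old WT against a floor of 3 counts per library, but were above background in 1 old WT library. Tmem52 was not called without old WT library 3 (6.14), nor Olfr1010 without old WT library 1 (4.73).

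In total 12056 of 32582 genes differed between old and young WT, 6060 higher (50.3%) and 5996 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). With upper-quartile factors 61.6% of the calls were higher and with total counts 95.2%, and without old WT library 1, 2 or 3 the count was 4286, 4635 or 3695. The higher share was 61.7% by DESeq2, 66.1% with a stricter filter and 38.7% with none. At an adjusted p under 0.01 it was 19.4%, after thinning 87.9% (9595 higher, 1322 lower) and at matched depth and background 20.5% (704 higher, 2722 lower), where 1660 of the 12056 genes had the opposite sign. After background removal 12 genes passed, 5 of them lower: Fosb, Klf4, Klf6, the histone gene H3f3b and the polyamine enzyme gene Odc1 (the last 2 chosen after their values were seen).

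**Figure D2:**
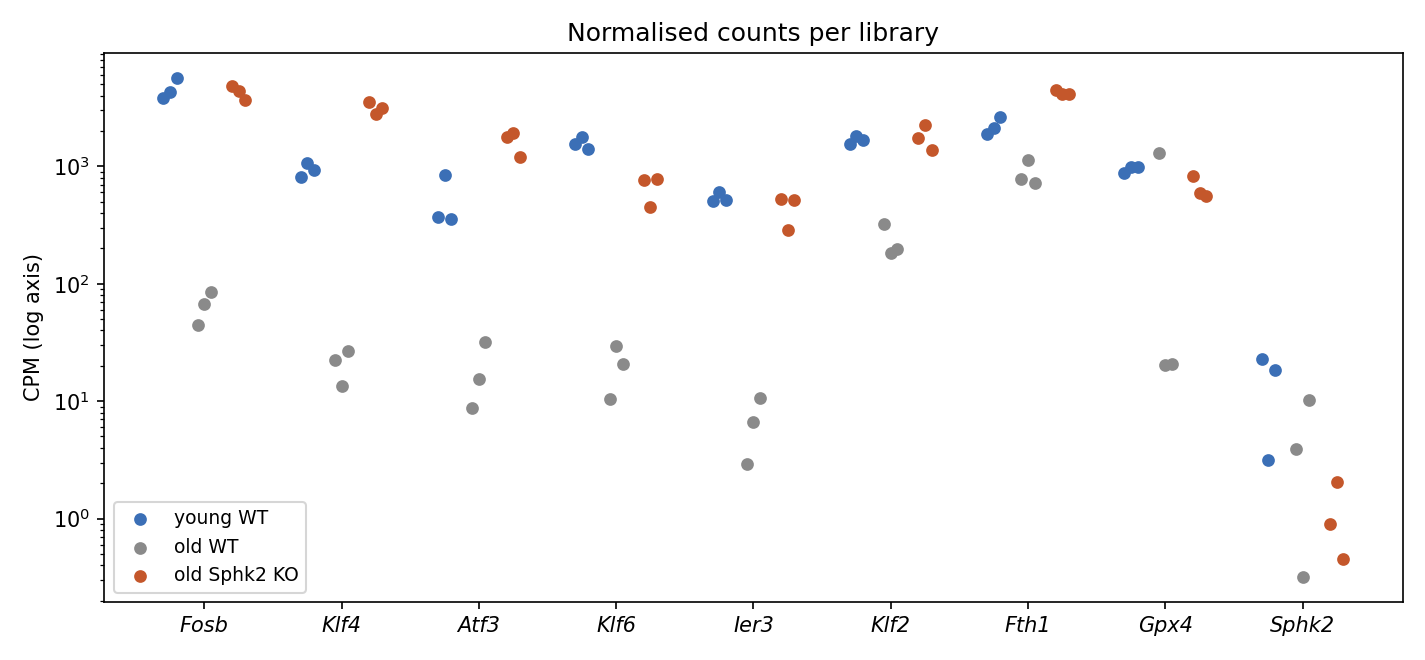
CPM on a log axis for 9 genes, with 1 point per library. Fosb, Klf4, Atf3, Klf6, Ier3, Klf2 and Fth1 lie lower in each old WT library than in every young WT and old KO library. Gpx4 has 1297 CPM in 1 old WT library and 20.3 and 20.9 CPM in the others, and Sphk2 ranges from 0.318 to 22.8 CPM.

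The comparison of old KO with old WT asks what loss of Sphk2 changes in old stem cells. Immediate early and heat shock genes led it: 12 of 34 members were called higher in old KO (27 adjusted over the list alone), 11 of them immediate early genes and 1 of the 6 heat shock genes. Klf4 had 3153 ± 396 CPM against 20.9 ± 6.94 CPM (SD, n = 3 each), a fold change of 9.23 ± 1.10 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0058). Fosb rose from 65.4 ± 20.1 to 4302 ± 571 CPM (7.98 ± 0.92, adjusted p = 0.0058), and Atf3, a stress-induced transcription factor, from 18.7 ± 11.7 to 1638 ± 379 CPM (8.44 ± 1.15, adjusted p = 0.0206, same test). Ier3 (8.12 ± 1.22), Klf6 (7.01 ± 1.08) and Klf2 (4.75 ± 0.89) were called higher as well. For 31 of the 32 members above background in all young WT libraries the mean was higher in old KO than in old WT. This was not particular to the list. Of 1442 genes above background in all young WT and old KO libraries, 98.5% were higher in old KO with TMM factors. In 21 of the 32 members the old KO and young WT ranges overlapped. By chance 10% of unchanged genes would have ranges apart, so this overlap was less frequent than unchanged levels would give. The median of these 32 members was 4.30, against 2.79 for random lists of equal young WT expression (2.14 to 3.70; adjusted permutation p = 0.0308). By camera the list was higher than other genes (adjusted p = 2.1e-42, and 0.0033 with an estimated correlation). Most of these other genes were not above background, and their median was -0.02. Camera on the deposited counts therefore does not set the list apart from expressed genes in general. With background removed and an estimated correlation the list did not pass (camera adjusted p = 0.0592). Of the 9 runs without 1 library, Fosb kept its call in 4, Klf4 and Atf3 in 3, and Ier3, Klf6 and Klf2 in 2.

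Other genes with the largest called rises, each with an adjusted p between 0.0275 and 0.0460 in edgeR's quasi-likelihood test, were Sertad1 (8.17 ± 1.17), Fosl1, a further AP-1 gene (9.26 ± 1.75), Dctn3 (8.46 ± 1.60), Smim3 (8.21 ± 1.65), Rgs18 (8.14 ± 1.68), Mrfap1 (8.12 ± 1.44) and Herpud1, a gene of the unfolded protein response (8.42 ± 1.35; SE, n = 3 each for all). With Ddit3 (7.33 ± 1.25) and Manf (6.89 ± 1.28), Herpud1 made up the 3 called genes among 40 of the unfolded protein and integrated stress responses (11 over the list alone). Of 29 quiescence genes 4 were higher (15 over the list alone): Klf4, Klf6, Klf2 and Btg1, an inhibitor of proliferation (6.72 ± 1.30). The Klf genes are also members of the immediate early list. The p53 and senescence list had 3 of 35 higher (12 higher and 1 lower over the list alone), including Bbc3, which encodes the apoptosis inducer PUMA (6.24 ± 1.25), and Gadd45b (6.72 ± 1.36). F2r, a thrombin receptor (7.46 ± 1.23), and Rap1b (6.59 ± 1.11), from the megakaryocyte and platelet list, were called higher as well. None of these lists passed against random lists of equal young WT expression. The adjusted permutation p was 0.519 for the stress responses, 0.370 for quiescence, 0.270 for p53 and senescence and 0.68 for megakaryocyte and platelet genes. For comparison, 147 of 1442 genes above background in all young WT and old KO libraries were called. Other called genes were Pcna (7.87 ± 1.21), Id3 (6.46 ± 1.19), Smad7 (6.31 ± 1.23), the histone demethylase gene Kdm6b (6.64 ± 1.24), and Clu (7.65 ± 1.40) and Itga6 (5.86 ± 1.15) from the 50 genes reported as higher in old stem cells. Of the 9 runs without 1 library, these genes kept their calls in 2, those without old KO library 1 or 2, except for Klf4 (3) and Rgs18 (1).

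In the pathways of the series title few genes passed. Fth1 was the called gene among 35 ferroptosis suppressors (7 over the list alone) and rose from 875 ± 227 to 4247 ± 206 CPM, a fold change of 4.15 ± 0.85 (SE, n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0441). Fth1 kept this call in 0 of the 9 runs without 1 library and was not called with total counts (2.26) or after background removal (2.38). Gpx4 was not called (662 ± 146 CPM in old KO, 2.34 ± 1.32, adjusted p = 0.585), nor was Slc7a11, the cystine carrier, which stayed at background (-0.21 ± 0.85, adjusted p = 0.99998). Of 40 ferroptosis-promoting genes 2 were higher (4 over the list alone): Sat1, a polyamine enzyme gene (6.75 ± 1.25), and Map1lc3b, an autophagy gene (5.91 ± 1.10), while Acsl4 (4.49 ± 1.59) and Tfrc (2.94 ± 1.39) were not called. Ormdl3 was the called gene among 43 of sphingolipid metabolism (6.82 ± 1.35; 2 over the list alone), but it kept the call only without old KO library 2 among the 9 runs, and Sat1 and Map1lc3b only without old KO library 1 or 2. Of that list 6 members were above background in at least 2 old KO libraries. Sgpl1 (1.36 ± 1.15) and S1pr1 (4.79 ± 1.43) were not called. By camera the sphingolipid list was higher than other genes (adjusted p = 0.0188), but not with an estimated correlation (adjusted p = 0.0704 with an estimated correlation). The medians of the sphingolipid and ferroptosis lists lay within those of random lists of equal expression.

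Ribosomal protein and mitotic genes lay below genes of like expression. Ribosomal protein genes had a median of 2.01 against 3.55 for random lists (adjusted permutation p = 0.0044), and G2 and mitosis genes 0.10 against 2.07 (adjusted permutation p = 0.0158). Of 40 G2 and mitosis genes, 0 were above background in at least 2 old WT libraries and 5 in at least 2 old KO libraries. The median of that list therefore mostly compares reads near background. No gene of the second list was called by edgeR's quasi-likelihood test, and its member with the smallest p, Hmgb2, had 4.38 ± 1.27 (SE, n = 3 each; Benjamini-Hochberg adjusted p = 0.152). Neither Kit (4.16 ± 1.02, adjusted p = 0.0871) nor the antioxidant gene Prdx1 (5.89 ± 1.26, adjusted p = 0.0536) was called. By camera 25 of 37 lists were higher than other genes, and 20 kept the call with an estimated correlation. Besides the sphingolipid list, those that lost it were iron and haem (adjusted p = 0.0797 with an estimated correlation), mitochondrially encoded (0.144), ribosomal protein (0.0609) and fatty acid oxidation genes (0.0609). After background removal 6 lists were higher and 1 lower, and 0 kept the call with an estimated correlation.

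**Figure D3:**
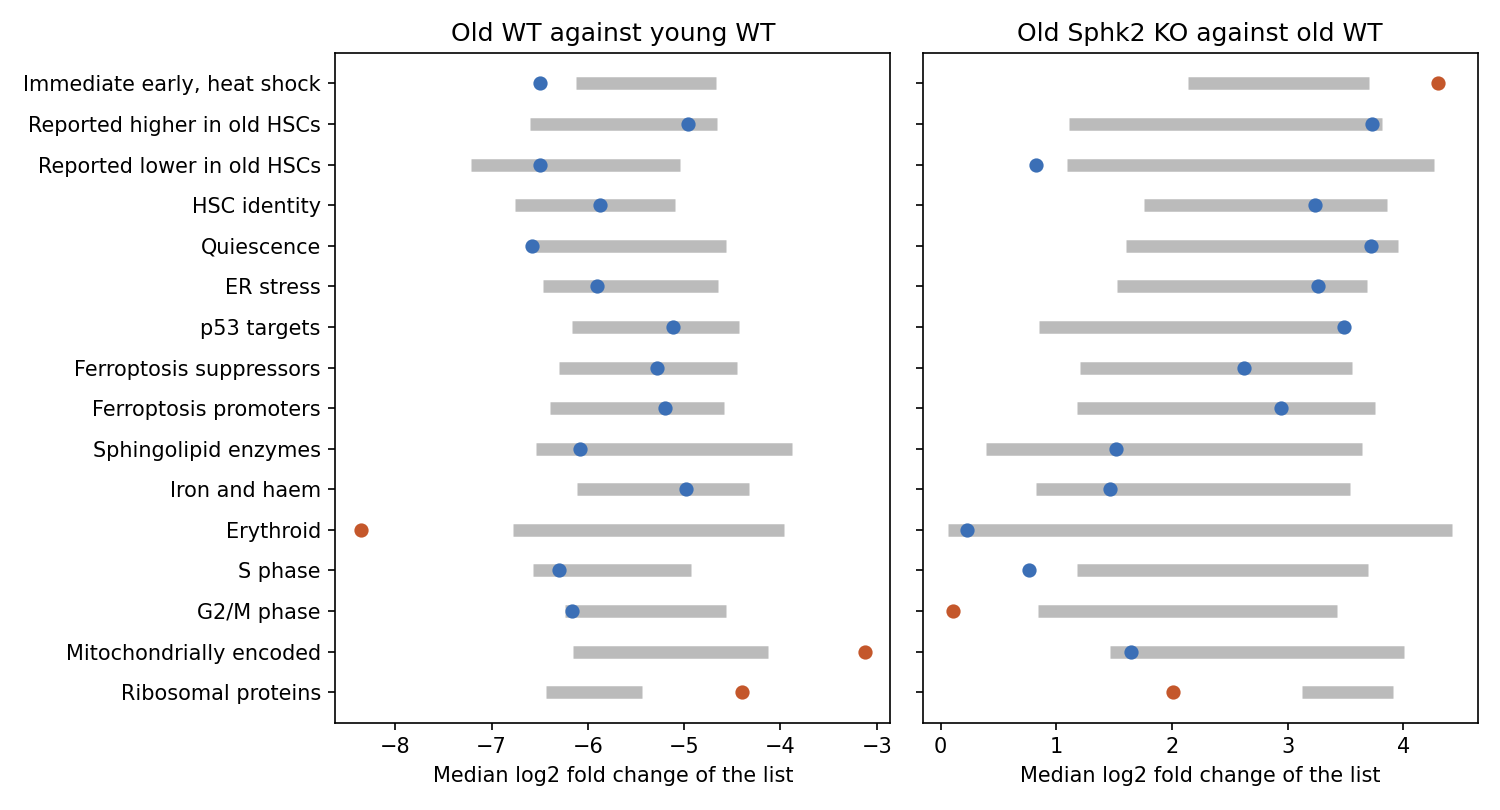
Median log2 fold change of 16 gene lists (points) with the central 95% of random lists of equal young WT expression (bars), for old WT against young WT (left) and old KO against old WT (right). Orange points have an adjusted permutation p under 0.05, and immediate early and heat shock genes in old KO are the only list shown above its bar there, with a median of 4.30.

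In total 149 genes were called higher in old KO and 0 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted; 3137 higher and 713 lower at an unadjusted p under 0.05, but 946 and 8726 with total counts). DESeq2 called 2030 higher and 151 lower and limma-voom 358 and 17. The count was 2 with DESeq2's, upper-quartile or total-count factors, where Klf4 (7.21) and Fosb (6.02) passed with total counts. It was 0 without young WT library 1, 2 or 3 (4630, 4400 or 4453 genes at an unadjusted p under 0.05) or old WT library 1 or 2 (2909 or 3065), 1 without old WT library 3, 3 without old KO library 3, and 15 after background removal (14 higher, 1 lower), among them Klf4, Fosb, Atf3, Sertad1 and, chosen after their values were seen, Odc1, H3f3b, Dnajb1, Junb, Tpm3 and Tpt1.

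Old KO and young WT differed in age and genotype together, and the comparison shows how far old KO libraries lay from young WT. Genes of cell division were lower in old KO: 17 of 40 G2 and mitosis genes (26 over the list alone) and 14 of 39 S phase genes (23 over the list alone). Of these lists 5 and 7 genes were above background in at least 2 old KO libraries, against 33 and 35 in young WT. Random lists of equal young WT expression were not drawn for this comparison. A fall of these genes is therefore not told apart from the lower number of genes detected in old KO. Mki67, a proliferation marker, had 4.98 ± 1.52 CPM in old KO and 103 ± 15.9 CPM in young WT (SD, n = 3 each), a fold change of -6.62 ± 1.27 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0298). Cdc20 (-8.02 ± 1.55) and Aurkb (-7.72 ± 1.55), which act in mitosis, and Rrm1 (-6.70 ± 1.22) and Mcm3 (-6.87 ± 1.25), which act in DNA replication, had the same adjusted p. So did the chromatin enzyme genes Dnmt1 (-6.86 ± 1.31) and Ezh2 (-7.32 ± 1.33). Of 28 genes reported as lower in old stem cells, which include Mcm3 and Ezh2, 11 were lower (15 over the list alone; camera adjusted p = 1.1e-09, and adjusted p = 0.0057 with an estimated correlation). The genes named here kept their calls in 6 of the 9 runs and lost them without old KO library 1, 2 or 3.

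Erythroid genes were lower too, with 7 of 18 called lower and 2 higher (10 and 4 over the list alone), among them Epor, the erythropoietin receptor (-8.46 ± 1.69), and Gata1 (-8.10 ± 1.93; SE, n = 3 each; -4.74 without young WT library 1). Of the erythroid list 1 gene was above background in at least 2 old KO libraries, against 11 in young WT. By camera that list had an adjusted p of 0.0213, and adjusted p = 0.0604 with an estimated correlation. Of 50 genes reported as higher in old stem cells 3 were higher and 2 lower (2 and 1 over the list alone). That list was not called by camera (adjusted p = 0.631), and its mean minus that of other genes was 0.080 and its median minus theirs -0.17. In the libraries with background removed the same list was higher than other genes, by a mean of 2.90 (camera adjusted p = 6.2e-06, and adjusted p = 0.0749 with an estimated correlation). In all, 27 of 37 lists were lower than other genes and 1 higher, stroma and endothelium (1 of 20 genes called; adjusted p = 0.0403, and adjusted p = 0.144 with an estimated correlation). With an estimated correlation 24 kept the call, and the mitochondrially encoded list was among those that lost it (0.144). After background removal 6 lists were higher and 4 lower, and 0 kept the call with an estimated correlation. Mogs (-9.36 ± 1.35) and Rab9 (-9.39 ± 1.61) were among the largest falls. Of 34 immediate early and heat shock genes 1 was called lower (0 over the list alone), Klf6 (-3.27 ± 0.91; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0382). Fth1 was not called (-1.13 ± 0.75, adjusted p = 0.247, same test), although its mean CPM was higher in old KO than in young WT (4247 ± 206 against 2209 ± 373). TMM lay below total counts in this comparison by a median of 2.01 log2 units over all genes. Gpx4 was not called either (-2.63 ± 1.34, adjusted p = 0.146), while Kit (-3.53 ± 0.99, adjusted p = 0.0394) and S1pr1 (-5.76 ± 1.49, adjusted p = 0.0349) were lower. Klf6 and Kit kept these calls in 0 of the 9 runs without 1 library, and S1pr1 in 3, those without young WT library 2 or 3 or old WT library 2. Ribosomal protein genes had 21 of 87 called lower and 1 higher (76 and 1 over the list alone; camera adjusted p = 2.4e-30, and adjusted p = 0.0923 with an estimated correlation). Among them were Rps2 at -2.68 ± 0.72 and Rplp1 at -2.58 ± 0.69, called in 2 and 3 of the 9 runs. With background removed the direction of the ribosomal protein list and the sign of both genes turned. Among genes called higher and above background in all 3 old KO libraries were Chac1, a glutathione-degrading enzyme gene (13.8 ± 7.44 CPM against 0.0450 ± 0.0780 CPM, 5.59 ± 1.48, adjusted p = 0.0357), and Cxcl2, a neutrophil chemokine (117 ± 115 against 0.266 ± 0.113 CPM, 7.03 ± 2.08, adjusted p = 0.0431). Notch1 was higher as well (4.31 ± 1.25) and was above background in 2 old KO libraries, and Ptgs2, a marker of ferroptosis, (6.97 ± 2.05) was above background in 1. These calls depended on which libraries were used: of the 9 runs that leave out 1 library, Chac1 kept its call in 2 and Cxcl2, Notch1 and Ptgs2 in 1 each. Ptgs2 was at 1.53 without old KO library 3, and Chac1 at 10.57 without young WT library 1.

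In total 4155 genes differed, 2253 higher (54.2%) and 1902 lower, and 97.6% of those called higher were not above background in at least 2 old KO libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). With DESeq2's size factors 43.7% of the calls were higher, with upper-quartile factors 67.3% and with total counts 93.1%. It was 85.1% with a stricter filter, 42.3% with none and 72.7% with the 6 libraries compared. After thinning it was 96.4%, and at matched depth and background 0 genes were called higher and 4 lower (edgeR quasi-likelihood test, 1853 at an unadjusted p under 0.05). The count was 0 without old KO library 1, 2 or 3 (10830, 10429 or 11917 genes at an unadjusted p under 0.05). It was 1821 or 2740 without young WT library 1 or 2, 1066, 1133 or 849 without old WT library 1, 2 or 3, and 4 after background removal.

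The series title names rejuvenation, so the knockout difference in old cells was set against the ageing difference. All 149 genes called higher in old KO were among the 5996 called lower with age, a comparison that uses the same old WT libraries. Independent lists drawn from all 32582 tested genes would share 27.4, but both lists hold almost only expressed genes. Of the 149, 147 were above background in all young WT and old KO libraries. Of the 5996, 5725 were above background in at least 2 young WT libraries. Among expressed genes alone the expected overlap would be larger, so 27.4 is too low a baseline. In 10 simulations of unchanged groups 0 genes had opposite calls, but this 0 gives no baseline. With the fitted dispersions used there, the test recovered 0% of genes changed even 64-fold in old KO against old WT. The value of 27.4 leaves out expression level and the shared libraries, and the simulations leave out the effects. Part of the overlap may therefore come from the shared libraries or from expression level. Klf4, Fosb, Atf3, Fth1 and Pcna are among them, and 10 of the 149 were still called lower in old KO than in young WT. Across 32582 genes the fold changes had a correlation of -0.668 and a covariance of -2.48, where unchanged groups that share the old WT libraries gave -0.390 ± 0.005 and -0.517 ± 0.012 (SD of 100 simulations; genes are not independent replicates). With different old WT libraries in the 2 comparisons the correlation was between -0.538 and -0.446 and the covariance between -2.32 and -1.98. After background removal the correlation was -0.622, where unchanged groups gave -0.508, and with no shared library it was between -0.206 and -0.181. The 50 genes reported as higher in old stem cells, lower than other genes in old WT against young WT (but not after background removal, mean 0.25 above others, camera adjusted p = 0.834), were higher than other genes in old KO against old WT (camera adjusted p = 3.6e-10, and adjusted p = 0.0057 with an estimated correlation). After background removal their mean was 2.65 above other genes (camera adjusted p = 3.1e-04, and adjusted p = 0.0865 with an estimated correlation). The 28 genes reported as lower in old stem cells, lower than other genes with age (after background removal camera adjusted p = 0.427), did not pass in old KO against old WT (mean 0.10 above other genes, camera adjusted p = 0.680). Set against random lists of equal young WT expression, neither list passed. The 50-gene list had an adjusted permutation p of 0.477 with age (median -4.96 against -5.64) and 0.298 in old KO against old WT (3.73 against 2.39). For the 28-gene list these were 0.788 (-6.49 against -6.23) and 0.133 (0.83 against 2.80).

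**Figure D4:**
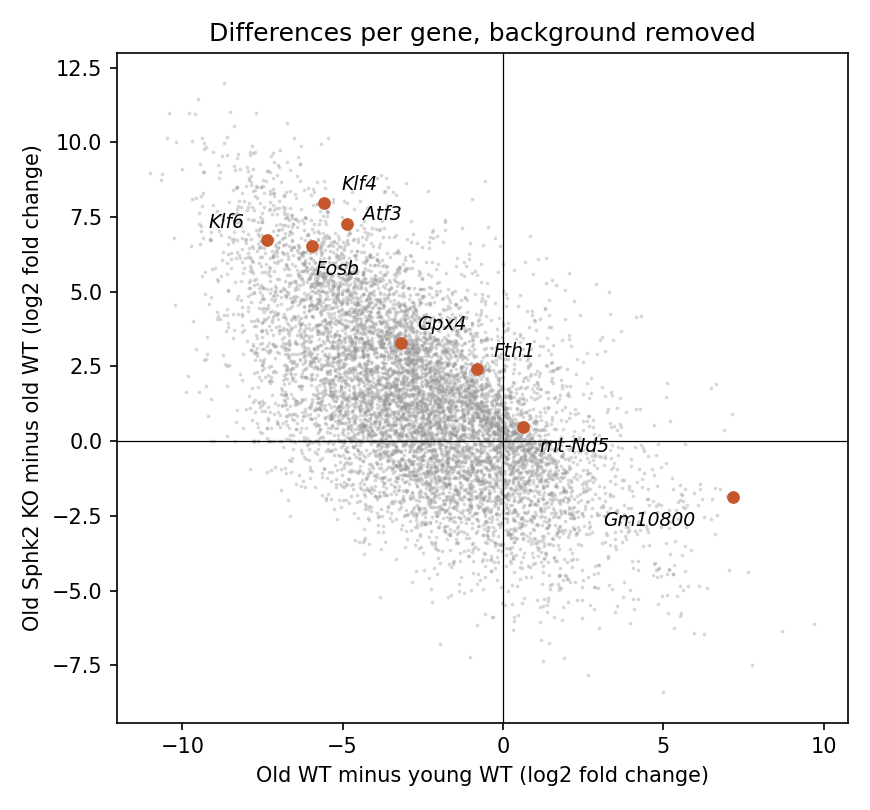
Log2 fold change of old KO against old WT (vertical axis) and of old WT against young WT (horizontal axis) after background removal, with 1 grey point for each of 8582 genes and 8 genes in orange. Klf4, Fosb, Klf6 and Atf3 lie at the upper left, lower with age and higher in old KO, and the correlation across genes is -0.622, where unchanged groups that share the old WT libraries give -0.508.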

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

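The tests of genomic reads, depth, RNA molecules and shared libraries below were chosen after the results were seen, while the splits of the libraries were fixed before.

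Counts outside annotated genes, which no comparison uses, averaged 83.6% of all counts in old WT and 54.5% in old KO libraries, against 10.3% in the young WT control libraries, and this signal above the controls is why they are given here. Of the genes called higher with age, 99.2% were not above background in at least 2 old WT libraries. The 7 genes called higher after background removal, such as Gm10800, varied by a median of 2.37-fold per unit of background density, against 289-fold in CPM. Among these, Gm10718 and Gm10717 were not called in the main test. Reads of genomic DNA may therefore account for the genes called higher. Depth alone is argued against as the whole cause, since 10917 genes were called after every library was thinned to the smallest total, 4643 of them among the 12056, but the genes called lower went from 5996 to 1322, so depth stays open for part of them. Of abundant young genes seen in any old WT library, 73.1% were above background in only 1 or 2 of the 3 (40.1% in old KO), so few RNA molecules read per library may account for genes called lower. A lower RNA content of old stem cells stays open, untested, as do age itself and the day and handling of each sort, which the labels do not give.

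Immediate early and heat shock genes in old KO against old WT form the next pattern. If few RNA molecules read in the old WT libraries were the whole cause, the list's median would lie within that of random lists of equal young WT expression, but it lay at percentile 99.9. The random lists hold genes drawn as if independent, while the list's members had an estimated correlation of 0.102, so the percentile alone cannot exclude this cause. With background removed and an estimated correlation the list did not pass (camera adjusted p = 0.0592). The list holds genes that tissue handling raises, and the time from death to sorting may have differed between groups, which the labels do not give and no value here tests. The knockout itself stays open as untested too, because the counts of Sphk2 do not separate the old groups.

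The opposite direction of the ageing and knockout differences across genes is the last pattern. The shared old WT libraries are argued against as the whole cause, since the covariance nearest 0 with no shared library was -1.98, below the simulated -0.517. Few RNA molecules read in old WT libraries stay open: detection of abundant genes in all 3 libraries lay 30.9% of the way from independence to full agreement in old WT and 32.1% in old KO, so this measure does not set old WT apart. A return of expression towards young WT in the knockout stays open, and these libraries do not separate it from a difference in library quality.

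Among the 10 splits of 6 libraries, 1, the real one, gave as many called genes in each comparison: 12056 with age (highest other 10), 149 in old KO against old WT (highest other 0) and 4155 in old KO against young WT (highest other 22). These splits are too few for a share under 0.05.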

How the results depend on the processing

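The analyses with background removed, thinned libraries and matched depth and background were chosen after seeing the data, and the others were fixed before. Under other settings, of which background removed with total counts and matched depth and background change 2 choices together, the 12056 genes that differed with age became 1870 at an adjusted p under 0.01, 23424 with total counts, 7072 with the replicate block, 12 with background removed, 17 with background removed and total counts, and 3426 at matched depth and background. The 149 genes of old KO against old WT became 2 at an adjusted p under 0.01, 2 with DESeq2 size factors, 2 with upper-quartile factors, 2 with total counts, 3 without mitochondrial and ribosomal protein genes, 271 with no filter on low counts, 247 with a stricter one, 2181 by DESeq2, 375 by limma-voom, 1340 by edgeR's likelihood ratio test, 892 by its exact test, 0 with the 6 compared libraries alone (edgeR quasi-likelihood test; 4592 at an unadjusted p under 0.05), 2 with the replicate block, 15 with background removed, 11 with background removed and total counts, and 2382 at matched depth and background. The 4155 genes of old KO against young WT became 0 at an adjusted p under 0.01 by edgeR's quasi-likelihood test (13312 at an unadjusted p under 0.05), 18448 with total counts, 6453 with a stricter filter, 9154 by DESeq2, 11745 by the likelihood ratio test, 0 with the replicate block (10310 unadjusted), 4 with background removed, 4 with background removed and total counts, 9944 after thinning and 4 at matched depth and background. Leaving out 1 library gave 3695 (without old WT library 3) to 11412 genes, 0 to 185 and 0 to 4482 in these comparisons. The cause was not tested, except that leaving out libraries and removing background leave fewer libraries or genes.

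The fold change of Sphk2 in old KO against old WT was 0.32 by limma-voom, 0.73 with the replicate block, 0.14 after thinning, 0.90 at matched depth and background, and -0.61 to 0.64 without 1 library, never past the threshold in these. Of the 329 genes that the naming rule gave and the test called, 150 kept their call with the replicate block, 7 with background removed, 7 with background removed and total counts, 111 at matched depth and background, and 158 to 267 without 1 library. The correlation of the ageing and knockout differences, -0.668, was -0.483, -0.446 and -0.538 with no shared library, -0.743 over genes called with age, -0.622 with background removed (unchanged groups -0.508, no shared library -0.206 to -0.181), and -0.685 to -0.584 without 1 library. Same-number libraries had residual correlations of -0.037 to 0.022 and other pairs -0.033 to 0.042, and 3 of 9 libraries correlated best with their own number. The numbers thus showed no pairing by this measure. Residuals from groups of 3 libraries cannot exclude a shared mouse, litter or day. Of 112 fold changes of genes named in a comparison, 100 kept their direction and side of the threshold by DESeq2, 106 by limma-voom, 78 with DESeq2 size factors, 55 with total counts, and 56 with the replicate block.

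Some fold changes past the threshold in at least 1 of the settings compared turned their sign, each with a cause that was not tested. In old WT against young WT these were Gpx4 (0.099 at matched depth and background), mt-Nd5 (0.10 with total counts, 0.61 with background removed, 0.63 with that and total counts, 1.15 matched), mt-Co1 (0.66 matched), Hlf (0.52, 1.02, 1.22 and 0.90 in the order of mt-Nd5) and Slamf1 (3.93 with total counts). In old KO against young WT they were Rps2 (0.0023) and Rplp1 (0.13), with background removed. Among fold changes past it in neither setting, 8 turned or reached 0 with total counts, 8 with background removed, 7 with that and total counts, 9 matched and 10 in runs without 1 library, such as Mecom with age (0.025 without young WT library 1) and Sgpl1 in old KO against old WT (-0.39 without old KO library 1). The 82 list calls numbered 81 to 83 without 1 library and 70 with an estimated correlation, and 19 lists passed with background removed (14 higher, 5 lower), of which 0 kept the call with an estimated correlation (immediate early and heat shock genes in old KO against old WT, adjusted p = 0.0592 with an estimated correlation). With background removed the direction by the test turned in 28 list calls (mean difference from other genes in brackets). With age these were the lists of genes reported higher in old stem cells (0.25), p53 and senescence (-0.015, its mean stayed lower), NF-kB inflammation (0.34), mitochondrially encoded genes (3.70), ribosomal proteins (2.19), fatty acid oxidation (0.12), DNA repair (0.47) and TGF-beta, BMP, Wnt and Notch signalling (0.35). In old KO against old WT they were iron and haem (-0.36), S phase (-0.74), interferon (-0.099), mitochondrially encoded (-1.66), ribosomal protein (-0.80) and chromatin genes (-0.17). In old KO against young WT they were ferroptosis suppressors (0.52) and promoters (0.46), antioxidant (0.77), stem cell identity (1.16), quiescence (1.04), p53 and senescence (1.16), immediate early and heat shock (2.00), unfolded protein response (1.69), mitochondrially encoded (2.04), nuclear oxidative phosphorylation (0.22), ribosomal protein (1.39), glycolysis (0.79), autophagy (0.69) and TGF-beta, BMP, Wnt and Notch genes (0.78). The mean but not that direction turned for unfolded protein response genes with age (0.012) and fatty acid oxidation genes in old KO against old WT (-0.067) and against young WT (0.049).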

Other observations

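The tests of sex, strain and background below were fixed before the data were examined, except for the detection of Ddx3y and Xist, which was chosen after the result was seen.

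Xist had 29.4 CPM in old WT and 0.837 CPM in young WT, a 35.2-fold difference, and 41.5 CPM was the background expected for it in old WT. The larger of the differences in Xist and the Y-linked genes between old KO and old WT was 6.28-fold. Ddx3y, a Y-linked gene, was above background in 3 young WT, 2 old WT and 2 old KO libraries, so the fewest libraries of either group with Ddx3y above background was 2 in both comparisons, and Xist was above background in 0. Of the 149 genes called higher in old KO, 100% lay outside 10 Mb of Sphk2, and 0 of the 411 tested genes within 10 Mb were called (Fisher exact p = 0.270). Nnt, which differs between substrains of the C57BL/6 mouse, was at background in both old groups, with a fold change of 0.28.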
